A study of Homo sapiens with 12 samples.

How the data were processed

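Nuclei of post-mortem human putamen from 12 donors were measured by single-nucleus RNA sequencing with the 10x Genomics Chromium 3′ V3 chemistry, per the labels. Per the labels' protocols, the tissue was cut out cold, guided by autoradiographs of dopaminergic markers, and nuclei were isolated by the 10x procedure. The labels give each donor a diagnosis, control (CTRL), Alzheimer disease (AD) or Parkinson disease (PD), and number the donors 1 to 4 within each group. Age, sex and other covariates of the donors were not used here.

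The values are deposited UMI counts per gene and barcode, whole numbers made by the authors without normalization, 1 matrix per donor. Per the submitters' processing notes, Cell Ranger 3.0.2, Seurat 3.08 and genome build hg38 were used, while the file headers of the deposited matrices name software version 3.1.0. How cell barcodes were chosen, and whether reads in introns and reads on the opposite strand were counted, is not given in the sources used here. Counts of antisense genes, overlapping genes and genes with near-identical copies are therefore uncertain. The matrices list 58288 genes, of which 55619 identifiers match GENCODE v29 with their version and 58025 without it. Coordinates are those of GENCODE v29 on hg38, counted from 1. Totals ranged from 8313082 to 45709181 UMIs per library, so a gene at a few CPM in a small class rests on few molecules.

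Nuclei with at least 300 genes and at most 5% mitochondrial UMIs were kept. Of 38929 barcodes, 20 were removed for few genes and 7061 for their mitochondrial share, and 31864 were kept. Predicted doublets (Scrublet as built into scanpy 1.11.5, with 0.8% expected per 1000 nuclei) numbered 726, or 2.28%, and were removed, which left 31138 nuclei. Counts were scaled per nucleus and log transformed, and 1992 variable genes, 30 principal components and 20 neighbours gave Leiden clusters (leidenalg 0.10.2, resolution 1.0) over all libraries without batch correction. A cluster took the name of the class whose fixed markers scored highest, at 0.4 or more. It stayed unnamed with under 3 markers detected in 10% of its nuclei, with over 50% predicted doublets, or with a median UMI count under 0.333 of that of its own libraries and none of the class's markers among its top 10 genes. MSN were typed as D1 or D2 by the fixed marker lists of each nucleus. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.

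The donor is the replicate. UMI counts were summed over the nuclei of a class in each donor with at least 20 such nuclei, for oligodendrocytes, astrocytes, microglia, OPC and MSN. Genes were tested by edgeR 4.0.16 (quasi-likelihood, robust, TMM, its expression filter) with the 3 groups in 1 fit, and the contrasts AD minus CTRL, PD minus CTRL and AD minus PD were drawn from it. Adjusted p values are Benjamini-Hochberg values within a class and contrast, two-sided, with a threshold of 0.05. Gene lists were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted within each class and contrast, wherever at least 4 members were measured. The 22 fixed lists cover heat shock chaperones, unfolded protein response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, cytosolic ribosomal proteins, metallothioneins, immediate early genes, MHC class I, MHC class II, interferon response, cholesterol biosynthesis, Alzheimer and Parkinson disease risk loci, reactive and homeostatic astrocyte genes, myelin genes, oligodendrocyte precursor genes, homeostatic and activated microglia genes, complement, dopamine signalling with striatal neuropeptides, and synaptic genes. The markers of the other classes were tested as lists in each class too. Donor levels of a list are the mean of its members' log2 CPM with a prior of 2. They were compared by exact permutation tests, two-sided. Shares of nuclei were compared by an exact permutation test of the sum of squares between the 3 groups, over 34650 arrangements of 12 donors and 1680 of the 9 linked ones, adjusted over 8 shares.

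Genes were named by a rule fixed beforehand. It takes, per class and contrast, the 3 genes with the largest rise and the 3 with the largest fall among those past the threshold with a mean log2 CPM of at least 5, and up to 10 list members past it. Where fewer than 3 genes passed, the 3 with the smallest p were taken. Of each list that camera called, the 3 members with the smallest p were taken, and they are printed for the class with the smallest adjusted p of that list. The rule leaves out sex-linked genes and clone-based names. The design, the lists, the markers, this rule and the first set of other settings were fixed before the data were examined.

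The gene test was tested on simulated data first, with counts drawn from the fitted means of each class and 200 genes changed in AD minus CTRL, 50 at each fold. It recovered 4% to 24% of genes changed 2-fold, 64% to 78% at 4-fold, 82% to 96% at 8-fold and 92% to 98% at 16-fold over the 5 classes, with 5 to 7 false calls among 126 to 147. Other splits of the real donors gave up to 109 genes (below), so these rates may not hold for them. The first set of other settings was RLE size factors, no expression filter, DESeq2 1.42.0, the donor number as a block, a depth covariate, a stricter filter of nuclei (at least 1000 UMIs and at most 1% mitochondrial), an estimated correlation, each donor left out in turn, doublets kept, a clustering resolution of 2.0, an arcsine scale for shares, and controls split between contrasts. Libraries were called linked where they shared more than 20 barcodes with another library. Settings built on this link, on shared barcodes, on a macrophage-like part of the microglia, on leaving out CTRL2 and PD4 or on leaving unnamed nuclei out of the total were chosen after seeing the data. Correlations of AD and PD fold changes were set beside 20 simulations of unchanged groups against the same controls. The values of some single genes are not reported here, though they stay in the list tests.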

Results

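Single nuclei were profiled from the putamen, the part of the striatum that receives most of its dopamine input from the substantia nigra, of 12 human donors. Each of 3 groups held 4 donors: controls (CTRL), donors with Alzheimer disease (AD) and donors with Parkinson disease (PD). There was 1 library per donor, so the donor is the replicate. The deposited matrices held 38929 barcodes and 306027036 UMIs, from 8313082 UMIs in CTRL2 to 45709181 in PD2. After filtering, 31138 nuclei remained, 7629 from controls, 12449 from AD and 11060 from PD. The median mitochondrial share of UMIs per library was 2.09% ± 1.31 in controls, 0.830% ± 0.282 in AD and 1.90% ± 1.67 in PD (SD, n = 4 each), and did not differ between the groups beyond the spread of the donors (exact permutation test over 3 groups, p = 0.362). The median UMI count per barcode did not differ either (exact permutation test, p = 0.775).

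Oligodendrocytes, the myelinating cells, made up the largest class with 13012 nuclei (41.8%). Medium spiny neurons (MSN), the projection neurons of the striatum, gave 7338 nuclei, astrocytes 4070, microglia 1842, vascular cells 1255, oligodendrocyte precursor cells (OPC) 1135, interneurons 554, ependymal cells 149 and T cells 80. A further 1703 nuclei (5.47%) lay in clusters that stayed unnamed. These unnamed nuclei made up 11.7% of the nuclei of the mean control donor, 4.11% in AD and 5.16% in PD (exact permutation test over 3 groups, p = 0.438). The classes are named from clusters by marker genes, so each is an inferred type. Microglia and OPC were 1 cluster each. The largest oligodendrocyte cluster was cluster 0 in controls (37.7%, 1103 nuclei of CTRL1, 2 to 8 per other donor). It was 22 in AD (58.7%, 20 to 1691 per donor) and 14 in PD (35.3%, 1655 of PD2, 2 to 34 per other donor). For astrocytes it was 3 in controls (55.4%) and AD (44.2%) and 23 in PD (49.0%, 614 of PD2, 20 to 36 per other donor). For MSN it was 1 in controls (63.9%) and PD (53.9%, 1280 of PD2, 12 to 93 per other donor). In AD it was 20 (40.2%, 864 of AD2, 6 to 309 per other donor). The median depth ranged from 2912 UMIs per nucleus in microglia and 2956 in oligodendrocytes to 20091 in MSN. CTRL2 had only 18 microglia and 19 MSN, under the minimum of 20 for a sum, so these 2 classes have n = 3 controls. Gene levels are given as mean ± SD over donors in CPM, the counts scaled to a common library total, and "against" sets the first group of a contrast before the second.

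The shares of the classes did not differ between controls, AD and PD beyond the spread of the donors. Oligodendrocytes were 39.1% ± 8.17 in controls, 42.4% ± 10.5 in AD and 44.2% ± 8.95 in PD (SD, n = 4 each; exact permutation test over 3 groups, p = 0.727). Astrocytes were 14.4% ± 5.23 in controls, 12.6% ± 4.67 in AD and 13.3% ± 2.83 in PD (exact p = 0.830). Microglia were 5.16% ± 3.23 in controls, 6.33% ± 1.36 in AD and 5.26% ± 2.36 in PD (exact p = 0.748). OPC were 4.69% ± 2.25 in controls, 3.49% ± 1.07 in AD and 3.61% ± 1.23 in PD (exact p = 0.575). MSN were 19.0% ± 12 in controls, 24.2% ± 3.55 in AD and 22.4% ± 7.30 in PD (exact p = 0.755). Interneurons were 1.48% ± 1.05 in controls, 1.85% ± 1.13 in AD and 1.59% ± 0.706 in PD (exact p = 0.865), and vascular cells 3.46% ± 0.576 in controls, 4.25% ± 1.23 in AD and 4.15% ± 2.26 in PD (exact p = 0.733). The interneuron share leaves out an unnamed cluster of 381 nuclei, predicted doublets included, led by NPY and SST, genes known from interneurons, whose best match was excitatory neurons. At the higher clustering resolution, where 64 nuclei led by NPY and SST were named interneurons and 320 led by CLSTN2 stayed unnamed, the exact p of the share was 0.801. Among MSN typed by their receptors and neuropeptides, the D1-type, which carries the dopamine receptor DRD1, made up 58.8% ± 12.4 in controls, 49.7% ± 3.85 in AD and 48.5% ± 4.61 in PD (exact p = 0.118). All 8 p values adjusted to 0.865. The D1-type share of CTRL2 rested on 13 typed neurons, and without CTRL3 the exact p was 0.0177. Within the 9 libraries linked by shared barcodes, described next, exact p values ranged from 0.107 to 0.839 over the 8 shares.

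**Figure D1:**
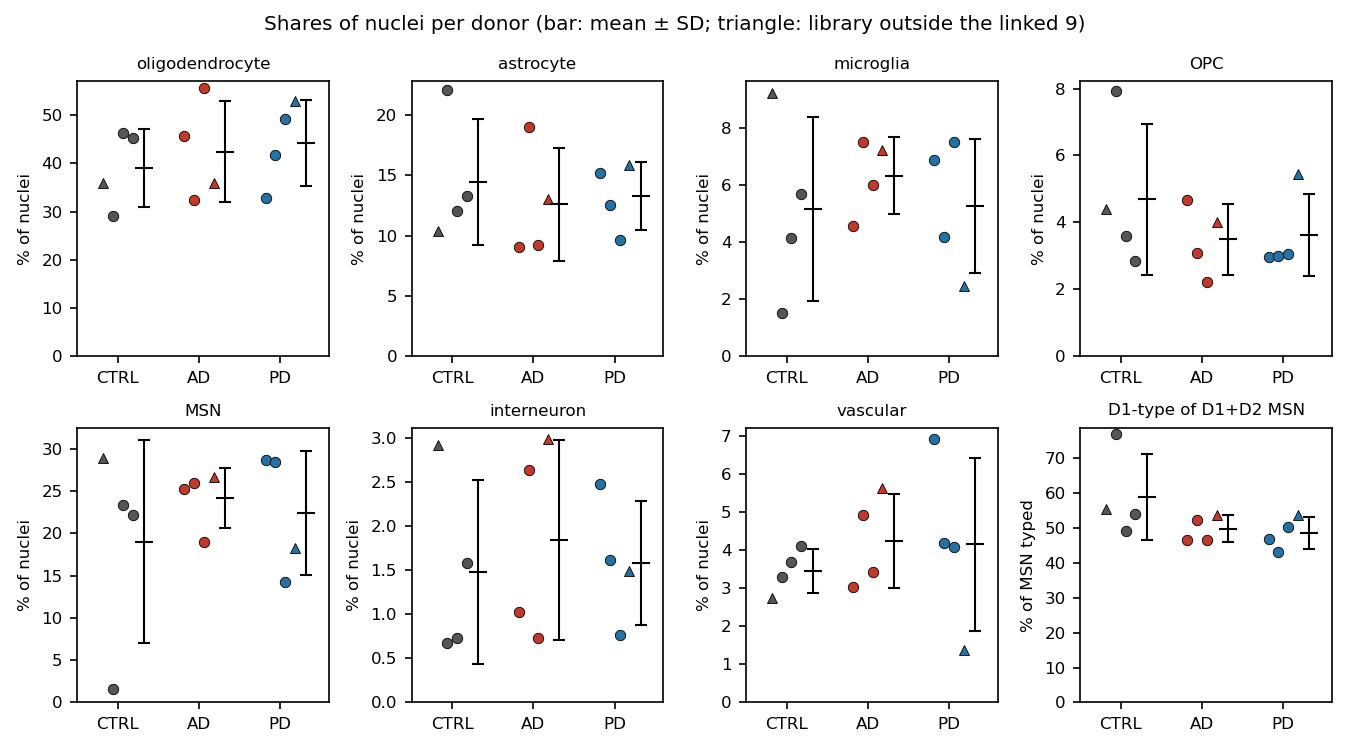
Percent of nuclei per class in each donor, and percent of D1-type among typed MSN, with the mean ± SD of 4 donors per group; triangles mark the 3 libraries outside the linked 9. The donors of the 3 groups overlap in every panel, and CTRL2 lies highest for astrocytes and lowest for MSN.

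The libraries fell into 2 sets by the cell barcodes they shared, a structure that the labels do not give. All 36 pairs among 9 libraries shared 50 to 286 barcodes (median 79), while the other 30 pairs, which involve CTRL1, AD4 or PD4, shared 0 to 11 (median 2.5). In total 2213 barcodes (5.68%) occurred in more than 1 library, as did 24.8% of the barcodes of CTRL2. The 9 linked libraries hold 3 donors of each group, so each gene count and list call was also tested within them. In microglia and MSN this left 2 controls, CTRL3 and CTRL4, as did leaving out CTRL1, since CTRL2 was under the minimum of 20. The 3 other libraries, 1 per group, are too few for a comparison of their own. Without barcodes found in more than 1 library, the MSN of CTRL4 went from 265 to 130 nuclei and from 8060698 to 2679676 UMIs. Those of PD1 went from 555 to 444 nuclei and those of AD1 from 492 to 421. In MSN without these barcodes, camera called 5 lists for AD minus CTRL (6 with them) and 5 for PD minus CTRL (4 with them).

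**Figure D2:**
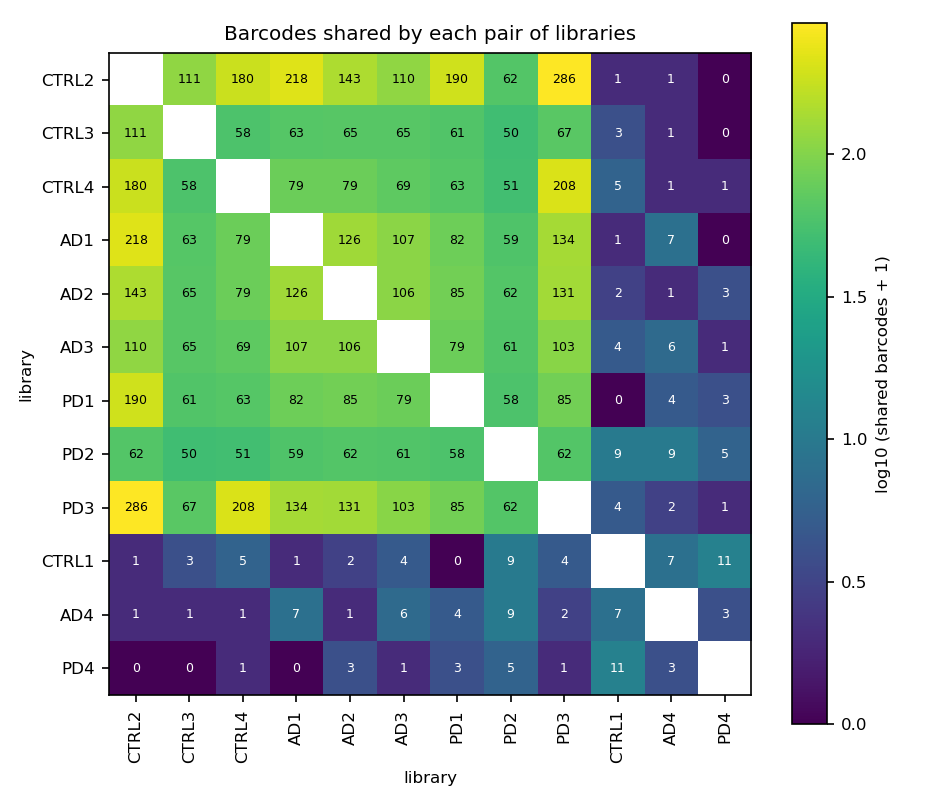
Number of cell barcodes shared by each pair of the 12 libraries, with color on a log10 scale of the number plus 1. The 9 libraries listed first share 50 to 286 barcodes per pair, and CTRL1, AD4 and PD4 share at most 11 with any other library.

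The design first asks how glia and MSN in AD differ from those in controls. In microglia, the resident immune cells of the brain, 5 genes fell in AD and 0 rose. WARS, the cytosolic tryptophanyl-tRNA synthetase (chromosome 14, 100333788 to 100376805), averaged 46.2 ± 3.81 CPM in AD (SD, n = 4) against 333 ± 98.5 in controls (n = 3), a log2 fold change of −2.86 (SE 0.42, edgeR quasi-likelihood adjusted p = 0.0395). RELB, a subunit of the transcription factor NF-kB (chromosome 19, 45001430 to 45038198), averaged 8.07 ± 1.85 against 59.2 ± 24.5 CPM (−2.90, SE 0.44, adjusted p = 0.0395). CCL2, a chemokine that attracts monocytes (chromosome 17, 34255218 to 34257203), averaged 0.257 ± 0.513 against 116 ± 107 CPM (adjusted p = 0.0403), from 126, 52 and 1 UMIs in the 3 controls and 0, 1, 0 and 0 UMIs in the 4 AD donors. Also lower were CD48, a surface protein of immune cells (chromosome 1, 160678746 to 160711851), with 1.28 ± 1.56 against 44.9 ± 12.4 CPM (−4.91, SE 0.73, adjusted p = 0.0395), and the actin-binding protein gene ABLIM3 (chromosome 5, 149141483 to 149260542), with 4.08 ± 2.65 against 41.1 ± 8.07 CPM (−3.50, SE 0.56, adjusted p = 0.0418). CD48 and ABLIM3 lie outside the rule for named genes and were chosen after their values were seen. Within the linked libraries (2 controls, 3 AD donors) 0 genes passed by edgeR, with WARS at a log2 fold change of −2.62 and an adjusted p of 0.0640. The count also went to 0 without CTRL1, without CTRL3 and without any 1 of the 4 AD donors, and to 21 without CTRL4. It was 0 as well with the donor number as a block, with the stricter filter of nuclei, with the depth covariate and with the library link as a term. At the higher clustering resolution, a part of the microglia led by genes known from macrophages held 298 of the 310 microglia of CTRL1 (96.1%), against 5.56% to 27.9% of those of the other donors. Without this part, an alternative chosen after seeing the data, CTRL1 and CTRL2 had fewer than 20 microglia, and with 2 controls left 0 genes passed, with WARS at a log2 fold change of −1.65 and RELB at −3.03. Whether this part holds macrophages or microglia in another state was not tested.

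**Figure D3:**
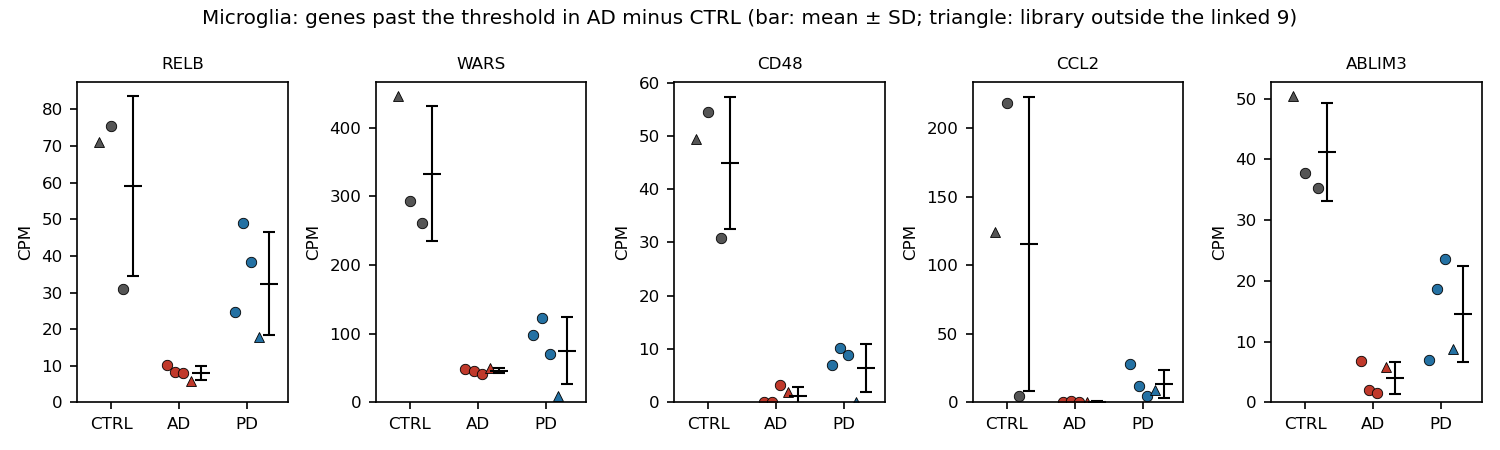
CPM of the 5 genes that passed in microglia, per donor, with the mean ± SD per group (3 controls, 4 AD, 4 PD); triangles mark libraries outside the linked 9. WARS lies at 46.2 ± 3.81 CPM in AD against 333 ± 98.5 in controls.

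Interferon response genes, which cells turn on against viruses, fell as a list in AD in all 5 classes. Their median log2 fold change was −1.62 in oligodendrocytes, −2.0 in astrocytes, −1.81 in microglia, −2.45 in OPC and −1.05 in MSN (camera adjusted p = 1.01e-12 to 0.00461, and adjusted p = 0.192 to 0.729 with an estimated correlation). Adjusted over the list alone, 11 of 14 measured members fell in microglia, 10 of 15 in astrocytes, 7 of 7 in OPC, 5 of 13 in MSN and 4 of 10 in oligodendrocytes, and 0 when adjusted over all genes by edgeR. In microglia IFI44L had 92.2 ± 46.6 against 618 ± 482 CPM and IFI6 11.5 ± 6.29 against 93 ± 124 CPM. Compared as donor levels, the list had an exact permutation p of 0.971 in oligodendrocytes, 0.657 in MSN and 0.0286 in the other 3 classes, and passed in none once adjusted over the lists of a class (adjusted p = 0.257 to 0.971). CTRL1 carried the highest level in every class, in oligodendrocytes a mean log2 CPM of 7.73 against 3.56 to 4.01 in the other controls. Without CTRL1 the median was 0.36 in oligodendrocytes and 0.09 in MSN, both no longer called, and −0.40 in astrocytes, −0.89 in microglia and −0.81 in OPC, which were still called (camera adjusted p = 5.77e-07 to 0.000438). The 9 linked libraries alone, which leave out CTRL1, AD4 and PD4, gave 0.14, −0.46, −0.86, −0.96 and 0.09 in the same order of classes as the first values, with the same 3 classes called. In MSN the median moved to −1.60 without CTRL3 and to −1.75 without CTRL4. Without CTRL1 the list in OPC was also called with an estimated correlation (adjusted p = 0.0248).

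**Figure D4:**
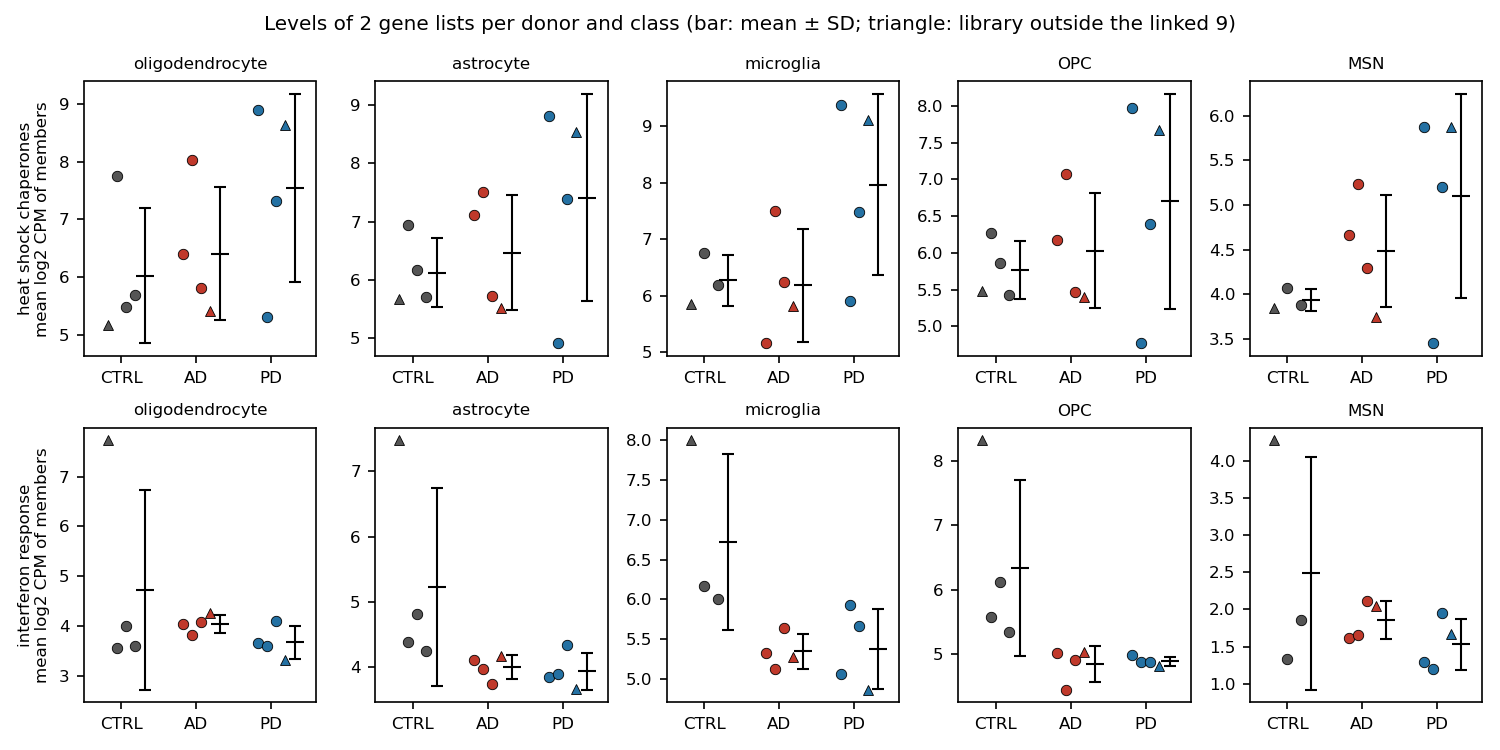
Mean log2 CPM of the members of 2 gene lists per donor in 5 classes, with the mean ± SD per group; triangles mark libraries outside the linked 9. CTRL1 lies highest for the interferon response genes in all 5 classes, and the PD donors spread most for the heat shock chaperones.

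MHC class I genes, which present peptides on the cell surface, fell as a list in AD in oligodendrocytes (median log2 fold change −2.80), astrocytes (−1.34), microglia (−0.84) and OPC (−1.65; camera adjusted p = 3.19e-07 to 2.92e-05, and adjusted p = 0.192 to 0.337 with an estimated correlation). Adjusted over the list alone, 9 of 12 members fell in oligodendrocytes, among them the peptide transporter gene TAP1 with 4.12 ± 1.02 against 47.0 ± 78.8 CPM, HLA-E with 4.41 ± 1.96 against 78.3 ± 146 CPM and HLA-B with 7.55 ± 2.30 against 92.1 ± 149 CPM. The HLA genes are close copies of each other and vary between people, so their counts are uncertain. Without CTRL1 the class I call ended in oligodendrocytes (median −0.36, adjusted p = 0.0628). Also without CTRL1, the median moved to −0.58 in astrocytes, −0.29 in microglia and −0.80 in OPC. Only the microglial call held in the linked libraries (median −0.29, adjusted p = 0.0308), with 0.274 in oligodendrocytes and 0.0745 in astrocytes and OPC. In microglia the MHC class II genes fell as well (median −0.74, 10 of 10 lower, camera adjusted p = 0.000327, and adjusted p = 0.559 with an estimated correlation), with their invariant chain CD74 at 796 ± 197 against 1323 ± 277 CPM. The call held in the linked libraries (median −0.65, adjusted p = 0.000152).

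Transcripts encoded in the mitochondrial genome fell as a list in AD in oligodendrocytes (−0.60), astrocytes (−0.73), microglia (−0.28) and OPC (−0.62), with camera adjusted p = 1.42e-06 to 0.0389 (adjusted p = 0.249 to 0.777 with an estimated correlation). In astrocytes MT-CO3 had 713 ± 354 against 1755 ± 777 CPM and MT-CO2 773 ± 389 against 1465 ± 624 CPM. All 4 calls held in the linked libraries (1.67e-10 to 0.00122). The library-wide mitochondrial share was also lowest in AD on average, at 0.830% against 2.09% in controls (exact permutation test over 3 groups, p = 0.362). The mitochondrial calls ended in microglia without AD1, AD3, CTRL3 or CTRL4 (medians −0.19, −0.11, −0.10 and −0.33, adjusted p = 0.115 to 0.529), and the median moved in oligodendrocytes to −0.95 without AD2 and −0.37 without AD3, in astrocytes to −1.20 without AD1, in microglia to −0.65 without AD2 and −0.44 without CTRL1 and in OPC to −0.37 without AD3 and −0.34 without CTRL2. Nuclear-encoded genes of oxidative phosphorylation rose in astrocytes (median 0.62, 22 of 22 higher) and MSN (0.33, 24 of 24). The camera adjusted p values were 0.00308 to 0.00989, and 0.651 to 0.686 with an estimated correlation. In MSN, NDUFB2 had 34.5 ± 9.22 against 23.5 ± 2.87 CPM and COX4I1 65.5 ± 24.6 against 46.7 ± 14.7 CPM. In the linked libraries the medians were 0.84 and 0.60 (adjusted p = 0.00111 and 0.000748). Without CTRL2 and PD4 the astrocyte median was 0.50, no longer called (adjusted p = 0.177). The oxidative phosphorylation calls ended in astrocytes without AD2 or CTRL2 (medians −0.13 and 0.50, adjusted p = 0.155 to 0.584) and in MSN without AD3 or CTRL3 (medians 0.18 and 0.20, adjusted p = 0.0524 to 0.113).

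In oligodendrocytes the myelin genes fell in AD (median −0.35, 17 of 18 lower, camera adjusted p = 3.79e-06, and adjusted p = 0.337 with an estimated correlation). Adjusted over the list alone 1 of them fell, the aspartoacylase gene ASPA (chromosome 17, 3472374 to 3503419), with 109 ± 34.7 against 219 ± 24.4 CPM (log2 fold change −1.0, SE 0.25). MAL, a myelin proteolipid gene, had 281 ± 36.0 against 382 ± 49.4 CPM and MBOAT1 4.42 ± 1.15 against 8.52 ± 2.79 CPM. The list fell in the linked libraries too (median −0.47, adjusted p = 2.3e-06). In OPC the myelin genes (−0.43) and the oligodendrocyte markers (−0.64) fell together (camera adjusted p = 0.00104 and 0.00121, and adjusted p = 0.214 and 0.206 with an estimated correlation). Among the markers MOG had 19.3 ± 9.35 against 46.9 ± 25.8 CPM and MBP 354 ± 104 against 553 ± 286 CPM. Both calls ended in the linked libraries (0.533 and 0.403). Without CTRL1 the myelin and marker calls ended (medians −0.10 and −0.27, adjusted p = 0.225 and 0.109), and the marker median moved to −1.02 without AD2. The precursor genes of OPC had a median of −0.21 (camera adjusted p = 0.0451, adjusted p = 0.192 with an estimated correlation, 0.0907 in the linked libraries), with LHFPL3 at 3702 ± 640.2 against 5221 ± 1434 CPM and SOX6 at 2109.7 ± 438 against 2709.8 ± 464 CPM. The precursor call ended without AD2, AD3, AD4, CTRL2 or CTRL3 (medians −0.14, −0.21, −0.22, −0.10 and −0.18, adjusted p = 0.0600 to 0.280).

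Astrocytes in AD had higher metallothioneins, the metal-binding proteins, with all 7 measured members above controls (median 1.65, camera adjusted p = 4.23e-06, and adjusted p = 0.262 with an estimated correlation). MT1G had 1157 ± 1344 against 159 ± 108 CPM, MT1E 947 ± 773 against 295 ± 98.0 CPM and MT1F 208 ± 177 against 66.7 ± 40.4 CPM. These genes are close copies in 1 cluster on chromosome 16, so reads could be split between them. Reactive astrocyte genes fell (median −0.87, 13 of 15 lower, camera adjusted p = 0.00498, and adjusted p = 0.469 with an estimated correlation). OSMR, an oncostatin M receptor, had 47.3 ± 14.0 against 115 ± 71.2 CPM and MAOB 197 ± 62.7 against 415 ± 274 CPM, while the glucocorticoid-induced FKBP5 of the same list had 603 ± 129 against 353 ± 177 CPM. Homeostatic astrocyte genes (median −0.19) and cholesterol biosynthesis genes (−0.17) fell too (camera adjusted p = 0.0308 and 0.0153, and adjusted p = 0.262 and 0.318 with an estimated correlation). Adjusted over the list alone, 1 of 16 homeostatic and 2 of 18 cholesterol genes fell, with the glutamate transporter gene SLC1A3 at 1507 ± 204 against 3548 ± 1791 CPM and TM7SF2 at 14.5 ± 3.61 against 33.0 ± 9.54 CPM. Oligodendrocyte markers in the astrocyte sums fell alongside (median −0.42, camera adjusted p = 0.0367, and adjusted p = 0.637 with an estimated correlation). The metallothionein and marker calls held in the linked libraries (2.4e-06 and 0.0315), and the reactive (0.124), homeostatic (0.0554) and cholesterol (0.101) calls did not. The metallothionein median moved to 0.86 without AD2. The reactive call ended without CTRL1 or CTRL3 (medians −0.55 and −0.58, adjusted p = 0.0826 to 0.152). The homeostatic call ended without AD2 or CTRL2 (medians −0.16 and −0.07, adjusted p = 0.109 to 0.205). The cholesterol call ended without AD2 or CTRL1 (medians −0.025 and 0.042, adjusted p = 0.109 to 0.225), and the median moved to −0.37 without CTRL2. The oligodendrocyte marker call ended without AD1, AD2, CTRL1, CTRL3 or CTRL4 (medians −0.22, −0.11, −0.37, −0.39 and −0.31, adjusted p = 0.0940 to 0.703), and the median moved to −1.31 without AD3 and −0.65 without CTRL2.

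Microglia in AD had lower cytosolic ribosomal protein genes, with all 35 measured members below controls (median −0.60, camera adjusted p = 2.24e-08, and adjusted p = 0.680 with an estimated correlation). RPS6 had 161 ± 58.5 against 364 ± 89.8 CPM and RPL15 110.2 ± 33.2 against 218 ± 39.6 CPM. Genes of activated, disease-associated microglia (−0.35), the unfolded protein response (−0.49) and cholesterol biosynthesis (−0.45) fell too (camera adjusted p = 0.0389 for each, and adjusted p = 0.680, 0.777 and 0.680 with an estimated correlation). Among them CD83, an activation marker, was the 1 member of its list that fell adjusted over the list alone, with 38.0 ± 28.4 against 157 ± 33.2 CPM, LGALS3 had 14.3 ± 10.3 against 34.9 ± 25.4 CPM and DDIT3 15 ± 15.1 against 45.4 ± 26.8 CPM. All of these calls held in the linked libraries (6.17e-09, 0.0457, 0.00162 and 0.000719). The activated call ended without AD1, CTRL1 or CTRL3 (medians −0.27, −0.17 and −0.26, adjusted p = 0.0561 to 0.174). The unfolded protein call ended without AD1, AD3, AD4 or CTRL3 (medians −0.27, −0.36, −0.47 and 0.40, adjusted p = 0.0608 to 0.527), and the median moved to −0.96 without AD2 and −0.88 without CTRL1. The microglial cholesterol call ended without AD2, AD4 or CTRL3 (medians −0.16, −0.36 and −0.25, adjusted p = 0.0779 to 0.404), and the median moved to −0.19 without AD3. Without the macrophage-like part, of the 8 lists called in microglia the ribosomal (median −0.67), unfolded protein (−1.06), interferon (−0.80) and MHC class II lists (−0.57) were still called (adjusted p = 5.99e-06 to 0.00258). The MHC class I (−0.25, adjusted p = 0.390), mitochondrial (−0.34, 0.0817), cholesterol (−0.61, 0.0620) and activated lists (−0.11, 0.898) were not.

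Camera called 4 further lists in MSN in AD. This fit lacks CTRL2, the highest control for heat shock in classes that keep it. The heat shock chaperones rose (median 0.61), as did the ribosomal protein genes (0.38), and the immediate early genes fell (−0.32; camera adjusted p = 0.00292, 0.00140 and 0.0473, and adjusted p = 0.651 for each with an estimated correlation). The chaperone genes DNAJB1 and HSPA8 had 30.1 ± 17.2 against 9.14 ± 1.13 CPM and 40.9 ± 21.2 against 14.7 ± 0.657 CPM, and the activity-dependent NR4A3 2.08 ± 1.55 against 6.0 ± 1.94 CPM. Astrocyte markers in the MSN sums fell (median −0.77, camera adjusted p = 0.0145, and adjusted p = 0.651 with an estimated correlation), with SLC1A2 at 23.2 ± 12.5 against 41.8 ± 5.84 CPM. The first 3 of these MSN calls held in the linked libraries (0.00615, 3.18e-07 and 0.0445) and the marker call did not (0.0830). The heat shock call ended without AD2 (median 0.21, adjusted p = 0.205). The ribosomal call ended without AD3 or CTRL3 (medians 0.09 and 0.20, adjusted p = 0.121 to 0.251), and the median moved to 0.60 without CTRL1. The immediate early call ended without AD1, AD4 or CTRL3 (medians −0.24, −0.38 and −0.26, adjusted p = 0.0850 to 0.176), and the median moved to −0.49 without AD3. The astrocyte marker call ended without CTRL1 (median 0.06, adjusted p = 0.318).

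Outside microglia, edgeR called 0 single genes in AD against controls. Unadjusted p values under 0.05 numbered 777 of 13798 genes in oligodendrocytes, 750 of 13500 in astrocytes, 714 of 9013 in microglia, 370 of 8184 in OPC and 1406 of 19678 in MSN. DESeq2 called 7, 3, 27, 0 and 14 genes in the same order. Among the genes that the naming rule admits, with a mean log2 CPM of at least 5, those with the smallest p that did not pass were, in oligodendrocytes, the GABA receptor gene GABRB1 (112 ± 74.3 against 23.8 ± 8.77 CPM), CTNNA2 (1251 ± 309 against 496 ± 137 CPM) and MCF2L2 (90.5 ± 7.07 against 51.9 ± 8.65 CPM). In astrocytes they were ATP1B2, a subunit of the sodium pump (321 ± 37.4 against 683 ± 104 CPM), RUBCNL (41.8 ± 6.88 against 18.2 ± 4.79 CPM) and the interferon-induced TRIM22 (10.4 ± 3.84 against 77.0 ± 94.8 CPM). OPC had C22orf34 (73.4 ± 29.1 against 19.3 ± 1.19 CPM), PRICKLE1 (107 ± 25.6 against 221 ± 50.2 CPM) and SH3RF3 (67.8 ± 6.85 against 156 ± 74.1 CPM), and MSN had GNL1 (31.4 ± 3.96 against 60.6 ± 12.4 CPM), MRPL41 (33.2 ± 5.30 against 81.8 ± 35.8 CPM) and NUP210L (64.9 ± 39.4 against 14.1 ± 10.6 CPM), with edgeR adjusted p = 0.534 for ATP1B2 and 0.697 to 0.878 for the others.

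In the comparison of PD with controls the heat shock chaperones, which refold damaged proteins, were called higher as a list in all 5 classes. Their median log2 fold change was 1.5 in oligodendrocytes, 1.82 in astrocytes, 2.02 in microglia, 1.27 in OPC and 1.46 in MSN (camera adjusted p = 1.87e-16 to 2.57e-08, and adjusted p = 0.290 to 0.477 with an estimated correlation). Adjusted over the list alone, 16 of 19 members rose in microglia, 14 of 22 in MSN and 0 in the other 3 classes, and over all genes 0 rose. In MSN, DNAJB1 (chromosome 19, 14514770 to 14529770) had 83.8 ± 71.5 against 9.14 ± 1.13 CPM (log2 fold change 3.19, SE 0.76), the inducible chaperone HSPA1A 93.6 ± 74.9 against 11.5 ± 5.14 CPM and CHORDC1 121 ± 84.4 against 32.7 ± 7.46 CPM. HSPA1A has a near-identical copy, HSPA1B, so its counts are uncertain. The 4 PD donors spread widely, and the difference of donor means from controls passed in none of the classes (exact permutation test, p = 0.171 to 0.286). PD2 had the lowest level of all donors in astrocytes (mean log2 CPM 4.91), OPC (4.77) and MSN (3.45). In oligodendrocytes CTRL2 (7.75) and AD2 (8.02) lay above PD3 (7.33). Within the linked libraries the medians were 1.02, 1.23, 1.73, 0.94 and 1.15 in the same order, all called (camera adjusted p = 5.81e-09 to 0.00170). In oligodendrocytes the unfolded protein response rose with it (median 0.56, 16 of 17 higher, camera adjusted p = 3.35e-08, and adjusted p = 0.290 with an estimated correlation). HSPA5, the chaperone of the endoplasmic reticulum, had 159 ± 103 against 59.4 ± 4.14 CPM and PDIA6 78.4 ± 32.6 against 44.1 ± 3.96 CPM, and the call held in the linked libraries (median 0.67, adjusted p = 8.42e-08). The heat shock median moved in oligodendrocytes to 2.36 without CTRL2.

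**Figure D5:**
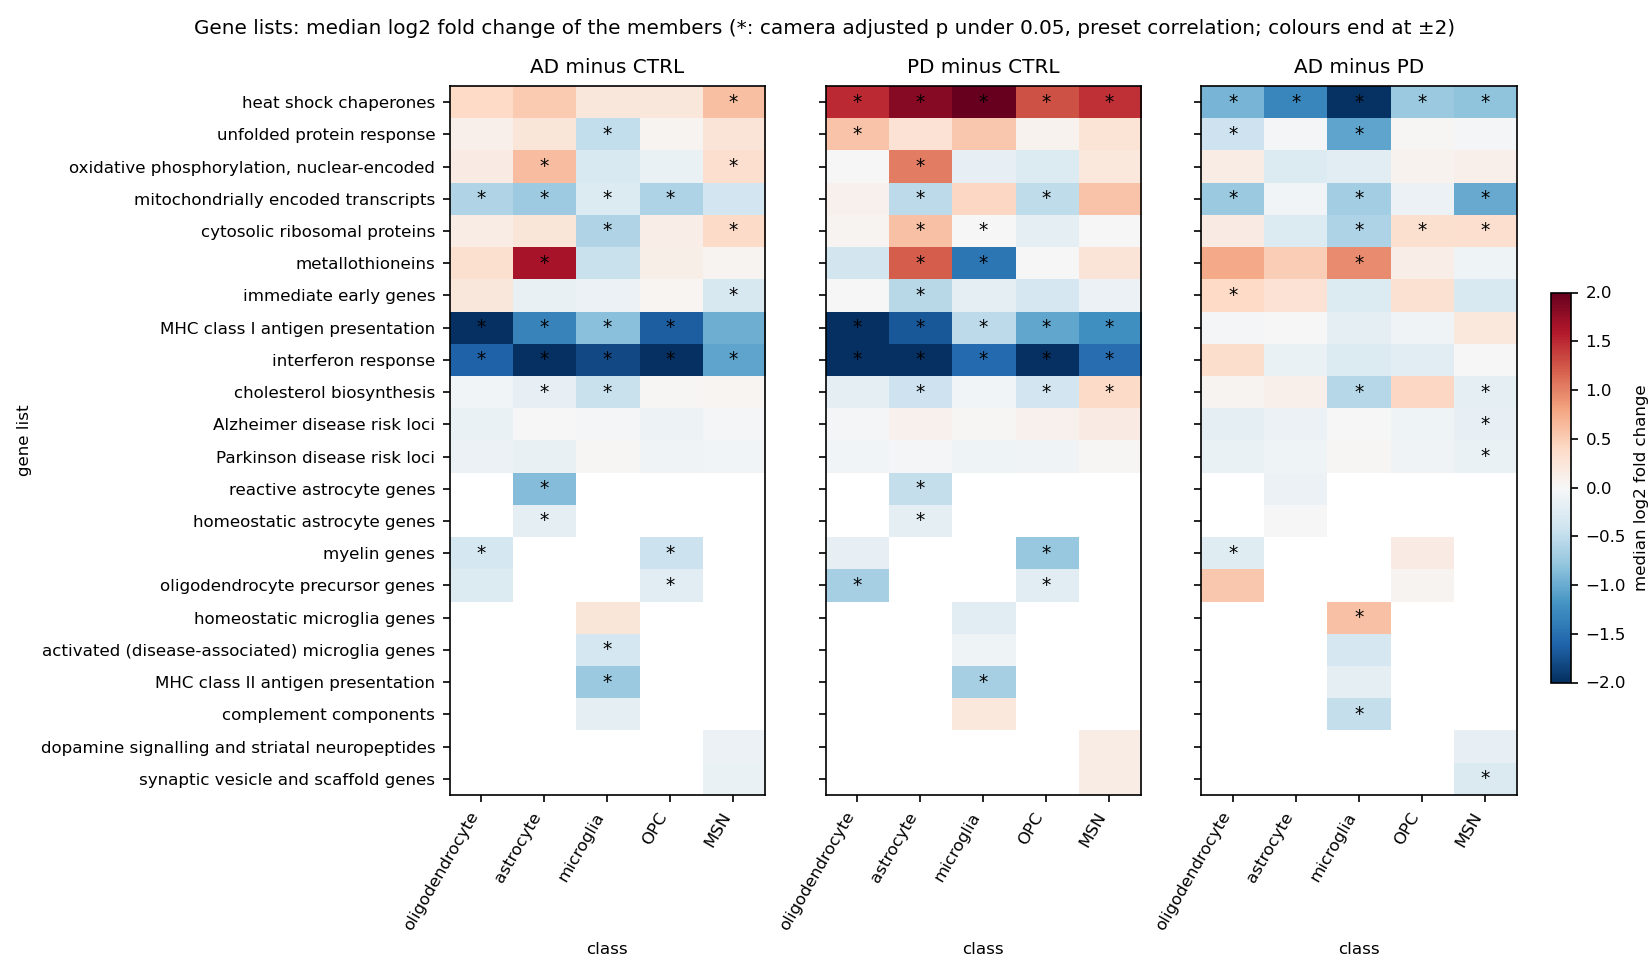
Median log2 fold change of the members of the 22 fixed gene lists in 5 classes and 3 contrasts, with color ending at ±2; asterisks mark a camera adjusted p under 0.05 with the preset correlation, and white cells were not tested. Heat shock chaperones are higher in PD than in controls in all 5 classes, and interferon response genes are lower in AD and in PD than in controls, with medians in oligodendrocytes of 0.36 for AD and −0.067 for PD, and in MSN of 0.09 and −0.18, once CTRL1 is left out.

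Interferon response genes fell in PD in all 5 classes, with medians of −2.09 in oligodendrocytes, −1.99 in astrocytes, −1.56 in microglia, −2.71 in OPC and −1.52 in MSN (camera adjusted p = 1.15e-11 to 1.44e-05, and adjusted p = 0.155 to 0.477 with an estimated correlation). Adjusted over the list alone 6 of 10, 10 of 15, 7 of 14, 6 of 7 and 6 of 13 members fell. IFI44L in microglia had 97.0 ± 77.3 against 618 ± 482 CPM. The exact permutation p of the donor levels was 0.457, 0.0571, 0.0286, 0.0286 and 0.229, and the interferon levels passed in none once adjusted (adjusted p = 0.162 to 0.971). Since 0.0286 is the smallest exact p possible, not passing after adjustment says little. The MHC class I genes fell in all 5 classes (medians −2.54, −1.69, −0.52, −1.03 and −1.22, camera adjusted p = 1.49e-09 to 0.00337, and adjusted p = 0.223 to 0.477 with an estimated correlation). In oligodendrocytes 9 of 12 members fell adjusted over the list alone, and TAP1 had 4.05 ± 1.52 against 47.0 ± 78.8 CPM. In microglia the MHC class II genes fell (median −0.67, camera adjusted p = 0.000522, and adjusted p = 0.425 with an estimated correlation), with HLA-DRA at 273 ± 163 against 502 ± 101 CPM, and still fell in the linked libraries (adjusted p = 0.00612). Without CTRL1 the interferon calls ended in oligodendrocytes (median −0.07, adjusted p = 0.523) and MSN (−0.18, 0.641). Also without CTRL1, the median moved to −0.47 in astrocytes, −0.39 in microglia and −1.11 in OPC. Without CTRL1 the list in OPC was also called with an estimated correlation (adjusted p = 0.0426). The MHC class I calls ended in microglia without CTRL1 or PD2 (medians −0.10 and −0.32, adjusted p = 0.0825 to 0.384), in OPC without CTRL1 (median −0.32, adjusted p = 0.0958) and in MSN without CTRL1 or PD2 (medians −0.011 and −0.84, adjusted p = 0.0641 to 0.804), and the median moved in oligodendrocytes to −0.12 without CTRL1, in astrocytes to −0.25 without CTRL1 and in OPC to −2.14 without PD3. The MHC class II median moved to −0.28 without CTRL3. In the linked libraries the interferon calls held in astrocytes (0.000304), microglia (0.00612) and OPC (0.000196) and ended in oligodendrocytes (0.813) and MSN (0.626), while of the MHC class I calls that of oligodendrocytes held (0.0343, median −0.06) and the other 4 did not (0.0618 to 0.655). Without the macrophage-like part of the microglia, the MHC class II (median −0.66, adjusted p = 0.00156) and heat shock lists (2.32, 7.87e-13) were still called in microglia, and the interferon (−0.53, 0.0542), MHC class I (−0.086, 0.825), metallothionein (−0.49, 0.659) and ribosomal lists (−0.048, 0.0542) were not.

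Astrocytes in PD had higher nuclear-encoded oxidative phosphorylation genes (median 1.02, 21 of 22 higher), ribosomal protein genes (0.59) and metallothioneins (1.21; camera adjusted p = 4.81e-05, 0.00284 and 0.00710, and adjusted p = 0.603, 0.635 and 0.562 with an estimated correlation). NDUFA1 had 122 ± 115 against 39.7 ± 15.3 CPM, RPL37 188 ± 171 against 68.0 ± 16.3 CPM and the brain metallothionein MT3 2186 ± 1998 against 879 ± 379 CPM. Mitochondrially encoded transcripts fell in astrocytes (−0.52) and OPC (−0.50; camera adjusted p = 2.81e-05 and 1.89e-05, and adjusted p = 0.483 and 0.313 with an estimated correlation), with MT-CO3 in OPC at 629 ± 376 against 1443 ± 248 CPM. These calls held in the linked libraries (1.82e-10, 1.07e-16, 0.000884, 1.52e-08 and 5.9e-21). Without CTRL2 and PD4 the metallothionein median was 0.89, no longer called (adjusted p = 0.193). The oxidative phosphorylation call ended without PD1 (median 0.20, adjusted p = 0.511). The ribosomal call ended without CTRL2 or PD1 (medians 0.35 and −0.20, adjusted p = 0.489 to 0.904). Its median moved to 0.91 without CTRL1. The metallothionein call ended without CTRL2 or PD1 (medians 0.96 and 0.22, adjusted p = 0.148 to 0.511). The mitochondrial calls ended in OPC without PD2 (median −0.21, adjusted p = 0.0873), and the median moved in astrocytes to −0.94 without PD3 and −1.03 without PD4 and in OPC to −0.21 without CTRL2, −0.29 without PD1 and −1.09 without PD4.

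Other astrocyte lists fell in PD. Reactive (−0.48) and homeostatic astrocyte genes (−0.18), cholesterol biosynthesis (−0.42) and immediate early genes (−0.56) were all called lower (camera adjusted p = 0.00730, 0.00730, 0.00282 and 0.0490, and adjusted p = 0.562, 0.236, 0.302 and 0.635 with an estimated correlation). The intermediate filament gene GFAP had 848 ± 229 against 1193 ± 355 CPM, glutamine synthetase GLUL 551 ± 100.3 against 891 ± 373 CPM and BTG2 22.1 ± 22.3 against 60.8 ± 49.9 CPM. Of these 4 only the homeostatic list was called in the linked libraries (adjusted p = 0.0166, against 0.356, 0.286 and 0.756). The reactive call ended without CTRL1, CTRL3 or PD2 (medians −0.28, −0.15 and −0.32, adjusted p = 0.156 to 0.498), and the median moved to −0.79 without PD1 and −0.82 without PD3. The homeostatic call ended without CTRL2 or PD1 (medians −0.08 and −0.14, adjusted p = 0.0517 to 0.25), and the median moved to −0.31 without CTRL3, −0.28 without PD2 and −0.28 without PD3. The cholesterol median moved to −0.68 without PD3. The immediate early call ended without CTRL1, CTRL3, CTRL4, PD2 or PD4 (medians −0.19, −0.48, −0.08, −0.23 and −0.29, adjusted p = 0.162 to 0.648), and the median moved to −1.10 without PD1.

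OPC in PD had lower myelin genes (median −0.76, 3 of 11 fell adjusted over the list alone) and lower oligodendrocyte markers (−1.06, 3 of 5; camera adjusted p = 1.54e-05 and 2.27e-06, and adjusted p = 0.155 and 0.130 with an estimated correlation). CNP, a myelin enzyme in both lists, had 134 ± 50.3 against 264 ± 77.4 CPM, ST18 26.6 ± 24.7 against 119.9 ± 62.7 CPM and CLDN11 16.3 ± 16.4 against 87.7 ± 91.9 CPM. Precursor genes (−0.21) and cholesterol biosynthesis (−0.39) fell in OPC (camera adjusted p = 0.00906 and 0.0237, and adjusted p = 0.130 and 0.374 with an estimated correlation). In oligodendrocytes the precursor genes (−0.66) and the OPC markers (−0.60) fell (camera adjusted p = 0.00177 and 0.0259, and adjusted p = 0.426 and 0.290 with an estimated correlation), with tenascin R, TNR, at 4.51 ± 2.63 against 15.2 ± 12.6 CPM and LHFPL3 at 69.9 ± 34.0 against 147 ± 92.0 CPM. In the linked libraries the myelin, oligodendrocyte marker and precursor calls in OPC held (0.00663, 0.00170 and 0.00246), as did the OPC markers in oligodendrocytes (0.0385), while the cholesterol list in OPC (0.0940) and the precursor genes in oligodendrocytes (0.118) were not called. The myelin median moved to −0.39 without CTRL1. The oligodendrocyte marker median moved to −0.67 without CTRL1. The OPC precursor call ended without CTRL2 or PD3 (medians −0.20 and −0.19, adjusted p = 0.0689 to 0.207). The OPC cholesterol call ended without CTRL1, CTRL4 or PD2 (medians −0.18, −0.35 and −0.34, adjusted p = 0.0640 to 0.114). The oligodendrocyte precursor gene call ended without CTRL1 (median −0.11, adjusted p = 0.396). The OPC marker call ended without CTRL1, PD1, PD2 or PD3 (medians −0.07, −0.53, −0.45 and −0.53, adjusted p = 0.0587 to 0.176), and the median moved to −1.02 without PD4.

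In MSN of PD donors the cholesterol genes rose (median 0.38, camera adjusted p = 0.000686, adjusted p = 0.483 with an estimated correlation, 0.00415 in the linked libraries). In microglia metallothioneins fell (median −1.45, camera adjusted p = 0.0454, and adjusted p = 0.754 with an estimated correlation), which ended in the linked libraries (adjusted p = 0.228). The metallothionein call ended without CTRL1, PD2 or PD3 (medians −0.33, −0.96 and −0.87, adjusted p = 0.101 to 0.939). The ribosomal list of microglia was called lower (camera adjusted p = 0.0492, and adjusted p = 0.834 with an estimated correlation) although its median was 0.0051 and its mean −0.032, and the linked libraries did not call it (0.641). This ribosomal call ended without CTRL3, CTRL4, PD2, PD3 or PD4 (medians −0.019, 0.023, 0.23, 0.05 and 0.21, adjusted p = 0.101 to 0.963), and the median moved to −0.11 without CTRL1 and −0.80 without PD1. The MSN cholesterol median moved to 0.23 without PD1.

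For single genes in PD against controls edgeR called 0 in each of the 5 classes, with 553 genes at an unadjusted p under 0.05 in oligodendrocytes, 714 in astrocytes, 473 in microglia, 511 in OPC and 1193 in MSN. DESeq2 called 0, 3, 4, 9 and 14. Within the naming rule, the genes with the smallest p in oligodendrocytes were the fatty acid desaturase FADS1 (43.5 ± 8.71 against 83.1 ± 9.45 CPM), HLA-C (8.95 ± 6.98 against 80.9 ± 88.8 CPM) and MYRIP (23.0 ± 9.59 against 83.9 ± 54.5 CPM), and in astrocytes ATP1B2 (355 ± 39.0 against 683 ± 104 CPM) and the adhesion receptor ADGRG1 (83.8 ± 21.8 against 162 ± 22.8 CPM). In microglia WARS had 75.4 ± 49.3 against 333 ± 98.5 CPM. OPC had SH3RF3 (51.2 ± 6.54 against 156 ± 74.1 CPM), GALNTL6 (10.3 ± 7.98 against 65.3 ± 26.9 CPM) and the BMP-binding BMPER (108 ± 27.3 against 302 ± 141 CPM), with adjusted p = 0.195 to 0.196 by edgeR. MSN had SNX31 (76.5 ± 36.3 against 10.7 ± 5.56 CPM). DPH6-AS1 in MSN (285 ± 64.9 against 115 ± 39.5 CPM) is antisense to a gene, so its count is uncertain.

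The direct comparison of the 2 diseases asks which changes tell AD from PD. Heat shock chaperones were lower in AD than in PD in all 5 classes (median log2 fold change −0.93 in oligodendrocytes, −1.31 in astrocytes, −1.97 in microglia, −0.74 in OPC and −0.80 in MSN, camera adjusted p = 1.48e-19 to 3.26e-05, and adjusted p = 0.507 to 0.957 with an estimated correlation). In microglia 14 of 19 members were lower adjusted over the list alone, and 0 over all genes. The co-chaperone BAG3 had 15.2 ± 13.8 against 239 ± 281 CPM, DNAJB1 26.1 ± 28.5 against 396 ± 412 CPM and HSPH1 152 ± 177 against 1531 ± 1335 CPM. The difference of donor means passed in none of them (exact permutation test, p = 0.143 to 0.429). In the linked libraries the call held in microglia (median −1.51, adjusted p = 1.13e-08) and astrocytes (−0.71, 0.0457) and ended in oligodendrocytes (0.0581), OPC (0.367) and MSN (0.142). The heat shock calls ended in OPC without PD1 (median −0.57, adjusted p = 0.133), and the median moved in oligodendrocytes to −1.61 without AD2 and −0.52 without PD1, in astrocytes to −0.79 without PD1, in microglia to −1.24 without PD1 and in OPC to −1.33 without AD2.

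The unfolded protein response was lower in AD in oligodendrocytes (−0.42) and microglia (−1.06; camera adjusted p = 0.000480 and 1.41e-06, adjusted p = 0.528 and 0.507 with an estimated correlation, 0.00122 and 3.51e-09 in the linked libraries), with calreticulin, CALR, in microglia at 67.3 ± 68.2 against 252 ± 309.9 CPM. Mitochondrially encoded transcripts were lower in AD in oligodendrocytes (−0.74), microglia (−0.69) and MSN (−1.01; camera adjusted p = 0.000482, 0.000564 and 0.00626, and adjusted p = 0.528, 0.646 and 0.639 with an estimated correlation), with MT-CO2 in oligodendrocytes at 957 ± 427 against 1652 ± 783 CPM. None of these 3 was called in the linked libraries (0.112 to 0.248) or without CTRL2 and PD4 (0.221 to 0.491). The unfolded protein response median moved in oligodendrocytes to −0.22 without PD1 and −0.65 without PD2 and in microglia to −1.98 without AD2 and −0.32 without PD1. The mitochondrial calls ended in oligodendrocytes without PD4 (median −0.16, adjusted p = 0.217), in microglia without AD3 or PD4 (medians −0.42 and −0.06, adjusted p = 0.0886 to 0.491) and in MSN without AD1, PD3 or PD4 (medians −0.97, −0.88 and −0.47, adjusted p = 0.0593 to 0.484). Interferon response and MHC class I genes were not called in any class (camera adjusted p = 0.326 to 0.851 and 0.115 to 0.918).

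Camera called 5 more lists in microglia of AD against PD. Homeostatic microglia genes were higher in AD than in PD (median 0.58, 10 of 12 higher), with the purine receptor P2RY12 at 543 ± 285 against 217 ± 68.8 CPM and TMEM119 at 76.0 ± 24.9 against 38.5 ± 10.4 CPM. Metallothioneins were higher too (0.94), with MT1G at 58.7 ± 11.7 against 20.6 ± 28.1 CPM. Lower in AD were the ribosomal protein genes (−0.62), complement components (−0.48) and cholesterol biosynthesis (−0.57), with RPS19 at 382 ± 66.1 against 661 ± 378 CPM and C1QB, a chain of the first complement component, at 536 ± 138 against 934 ± 479 CPM. The camera adjusted p values of these 5 lists were 0.000584, 0.00535, 5.58e-05, 0.0246 and 0.0193 (adjusted p = 0.507 to 0.666 with an estimated correlation), and in the linked libraries they were 0.000744, 6.59e-06, 5.85e-10, 0.0267 and 0.00303. The homeostatic median moved to 0.30 without AD1. The metallothionein call ended without PD2 (median 0.54, adjusted p = 0.210). The complement call ended without AD3, PD1 or PD3 (medians −0.46, −0.20 and −0.47, adjusted p = 0.0797 to 0.315). The microglial cholesterol call ended without AD2, PD2 or PD3 (medians −0.44, −0.37 and −0.35, adjusted p = 0.331 to 0.380). The ribosomal call ended without PD1 (median 0.09, adjusted p = 0.168). Without the macrophage-like part 7 of the 8 lists called in microglia were still called, and the complement list (median −0.43, adjusted p = 0.0820) was not.

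In oligodendrocytes the OPC markers (0.75) and the immediate early genes (0.39) were higher in AD than in PD, and the myelin genes lower (−0.24; camera adjusted p = 0.00644, 0.0222 and 0.0163, adjusted p = 0.528, 0.528 and 0.580 with an estimated correlation, and 0.00912, 0.00155 and 9.04e-06 in the linked libraries). OLIG1, a transcription factor of the lineage, had 354 ± 39.0 against 230.2 ± 55.3 CPM, JUNB 14.1 ± 9.93 against 3.95 ± 1.79 CPM, ASPA 109 ± 34.7 against 188 ± 53.0 CPM and the myelin gene MOBP 683 ± 180.0 against 1015 ± 299.6 CPM. The OPC marker call ended without AD4 (median 0.64, adjusted p = 0.0503). The immediate early call ended without AD2, PD2 or PD3 (medians −0.016, 0.33 and 0.30, adjusted p = 0.137 to 0.317). The myelin call ended without AD1, AD2, PD2 or PD3 (medians −0.20, −0.10, −0.17 and −0.12, adjusted p = 0.0633 to 0.265), and the median moved to −0.38 without PD4.

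In MSN the synaptic vesicle and scaffold genes were lower in AD (median −0.28, 24 of 26 lower, camera adjusted p = 6e-05, adjusted p = 0.532 with an estimated correlation, 0.00188 in the linked libraries), with the NMDA receptor subunit GRIN1 at 179 ± 33.0 against 305 ± 135 CPM and synapsin SYN1 at 30.7 ± 6.53 against 58.7 ± 28.5 CPM. Lower in MSN were also cholesterol biosynthesis (−0.18), the genes at Alzheimer (−0.17) and Parkinson disease risk loci (−0.13) and the astrocyte markers (−1.03; camera adjusted p = 0.00294, 0.0320, 0.0392 and 0.0114, and adjusted p = 0.532, 0.289, 0.289 and 0.532 with an estimated correlation). The amyloid precursor gene APP had 748 ± 208 against 1188 ± 608 CPM, clusterin, CLU, 83.8 ± 10.3 against 188 ± 112 CPM and MAPT, which encodes tau, 194 ± 44.5 against 294 ± 124 CPM. These 4 lists were not called in the linked libraries (0.0789, 0.142, 0.0714 and 0.198), where the astrocyte marker GFAP turned from −1.90 to 0.027 in log2 fold change. Ribosomal protein genes were higher in AD in MSN (0.33) and OPC (0.32; camera adjusted p = 0.00108 and 0.00350, adjusted p = 0.639 and 0.930 with an estimated correlation, 0.000846 and 0.690 in the linked libraries). RPL10 in MSN had 62.5 ± 26.0 against 26.5 ± 4.28 CPM. The ribosomal calls ended in OPC without AD2, PD2 or PD4 (medians 0.12, 0.08 and 0.11, adjusted p = 0.294 to 0.528) and in MSN without AD3 (median 0.07, adjusted p = 0.178), and the median moved in OPC to 0.92 without PD1 and in MSN to 0.69 without PD3 and 0.20 without PD4. The MSN cholesterol call ended without AD4 (median −0.10, adjusted p = 0.127), and the median moved to −0.28 without AD1, −0.33 without AD3, −0.30 without PD3 and −0.31 without PD4. The Alzheimer locus call ended without AD1, AD2, AD3 or PD4 (medians −0.14, −0.18, −0.16 and −0.12, adjusted p = 0.0560 to 0.166), and the median moved to −0.30 without AD4 and −0.26 without PD3. The Parkinson locus call ended without AD1, AD3, AD4, PD1 or PD2 (medians −0.17, −0.12, −0.19, −0.08 and −0.10, adjusted p = 0.0520 to 0.0884), and the median moved to −0.20 without PD4. The astrocyte marker call ended without AD1, AD2 or PD4 (medians −0.84, −0.98 and 0.035, adjusted p = 0.0560 to 0.667).

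Lists that were not called in any class and contrast were the dopamine signalling and striatal neuropeptide genes in MSN (medians −0.12 for AD and 0.14 for PD against controls and −0.17 for AD against PD, camera adjusted p = 0.0695 to 0.646) and the markers of MSN, of vascular cells and of microglia in the sums of other classes that measured at least 4 of them (lowest camera adjusted p = 0.0590, 0.0585 and 0.0831). These were all 4 other classes for MSN markers, oligodendrocytes, astrocytes and MSN for vascular markers, and MSN alone for microglia markers. With 3 members measured, the microglia markers were not tested in oligodendrocytes, where their mean log2 CPM was 3.96 in CTRL1 against 0.96 to 1.58 in the other controls, 1.59 to 3.06 in AD and 1.09 to 2.95 in PD.

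Between AD and PD edgeR called 0 single genes in each of the 5 classes, with 833 genes at an unadjusted p under 0.05 in oligodendrocytes, 619 in astrocytes, 421 in microglia, 365 in OPC and 1538 in MSN. DESeq2 called 6, 1, 2, 0 and 1. Within the naming rule, the smallest p values in oligodendrocytes were those of the fatty acyl reductase FAR2 (67.4 ± 19.5 against 16.3 ± 6.46 CPM), FOLH1 (296 ± 35.8 against 459.9 ± 66.8 CPM) and MGAT3 (32.4 ± 8.70 against 62.5 ± 11.5 CPM). In microglia LY96, the co-receptor of TLR4, had 84.8 ± 26.7 against 220.0 ± 32.5 CPM and RELB 8.07 ± 1.85 against 32.5 ± 14.0 CPM. Astrocytes had the cadherin CDH10 (139 ± 7.12 against 269 ± 61.8 CPM), the ceramide synthase CERS6 (119 ± 15.2 against 262 ± 109.6 CPM) and KHDRBS1 (56.7 ± 2.98 against 91.8 ± 15 CPM), OPC had TLL1 (46.4 ± 17.6 against 120.2 ± 34.9 CPM), DCAKD (104 ± 48.3 against 32.2 ± 10.9 CPM) and AKR1E2 (51.5 ± 7.28 against 19.4 ± 5.21 CPM), and MSN had CCDC59 (31.2 ± 7.02 against 60.2 ± 18.7 CPM). ALOX12-AS1 in microglia (67.6 ± 26.6 against 20.4 ± 5.53 CPM) and SNAP25-AS1 in MSN (164 ± 67.6 against 76.9 ± 8.0 CPM) are antisense genes, so their counts are uncertain. The edgeR adjusted p values of these genes ranged from 0.559 to 0.959.

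Whether AD and PD move the same genes was read from the log2 fold changes of both against the same controls, across genes, which are not independent replicates. Pearson's r was 0.501 in oligodendrocytes, 0.546 in astrocytes, 0.618 in microglia, 0.551 in OPC and 0.519 in MSN. Simulated unchanged groups against the same controls gave 0.527, 0.512, 0.590, 0.519 and 0.578. The covariance was 0.116, 0.148, 0.234, 0.105 and 0.159 in the same order, against 0.0968, 0.111, 0.158, 0.0830 and 0.125 in the simulation, an excess of 0.0192 to 0.0758. With the controls split between the 2 contrasts, r ranged over the 6 splits from −0.191 to 0.204 in oligodendrocytes, −0.127 to 0.304 in astrocytes and −0.158 to 0.234 in OPC. The covariance averaged over the splits was −0.00572, 0.0226 and 0.00945, against an excess of 0.0192, 0.0373 and 0.0218 in the same classes. The 3 controls of microglia and MSN were not split here. In each class part or all of the excess may come from the shared controls.

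Of the 273 tests of a list in a class and contrast, camera called 93 with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.130, and without CTRL1 the interferon list in OPC passed it in both diseases. Tested on the donors' mean list levels instead, 11 had an exact permutation p under 0.05, where the smallest possible value is 0.0286, and 0 passed after adjustment (lowest adjusted p = 0.162). Of the 93 calls, 10 had an exact p under 0.05, and 38 were kept without each donor in turn.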

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

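The tests of explanations, of libraries linked by shared barcodes and of other splits in this part were chosen after the results were seen. The first pattern is a cluster of 165 nuclei with genes of dopamine neurons, whose cell bodies do not lie in the putamen. The dopamine transporter gene SLC6A3 had 356 CPM there against 0.0128 CPM in MSN, the vesicular transporter SLC18A2 969 CPM, KCNJ6 2300.3 CPM and tyrosine hydroxylase, TH, 188 CPM. Of these nuclei 164 carried a barcode found in all 9 linked libraries, 99.39% of the cluster, and the cluster held 20 distinct barcodes. Dopamine neurons of each donor would not share their barcodes across 9 libraries, and a source library among the 12 would hold far more UMIs per barcode than the others, while the highest ratio of the top to the median copy was 1.829. Reads moved between libraries from a source outside these 12 remain as a candidate explanation, and other barcodes of the linked libraries could carry such reads too.

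The second pattern is the interferon response in CTRL1. The mean log2 CPM of its interferon list in oligodendrocytes was 7.73 against 3.56 to 4.01 in the other controls. RNA from microglia in the sums is argued against, since the interferon genes lay closer to their microglial level than the microglial markers did by a median of 5.6538 on the log2 scale in oligodendrocytes, 5.3074 in astrocytes, 5.298 in OPC and 4.9374 in MSN. A technical difference of the 3 unlinked libraries is argued against too, since the other 2 of them lay together above every linked library in 0 of 5 classes, PD4 in none and AD4 only in oligodendrocytes (4.26 against at most 4.10). No biological explanation was tested, and a difference of this donor or library alone stays open.

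The third pattern is the heat shock list, whose donor levels moved together across classes (Pearson's r from 0.835 to 0.983 over 10 pairs of classes). A technical difference of the unlinked libraries is argued against, because the linked libraries alone spanned at least 0.9591 of the whole range in each class. With the mitochondrial share of a library, the level in oligodendrocytes had Pearson's r = 0.499 (permutation p = 0.0985) and Spearman's rho = 0.259 (permutation p = 0.419), with adjusted p from 0.194 to 0.215 over the 5 classes. Without PD4 and CTRL2, the libraries farthest from the median share, r was 0.107, so the relation rests on them and this explanation stays open. Parkinson disease stays open as well, since the lowest of the 5 exact permutation p values for PD against controls was 0.17143.

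The remaining values each come from 1 donor that lies far from the other 3 of its group. Of 288 groups of 4 tested this way 19 (6.60%) had such a donor, 6 of them CTRL1, and chance gives about 1 in 20. PD4 had 5.45% OPC against 2.95% to 3.05%. CTRL2 had a median mitochondrial share of 4.02% against 1.26% to 1.72%. AD1 kept 78.7% of its barcodes against 91.8% to 93.2%. Unnamed nuclei were 32.7% in CTRL2 against 3.93% to 5.89%, and 6.55% in AD1 against 3.02% to 3.51%. PD2 gave 5081 nuclei against 1933 to 2101. In astrocytes the MHC class I list had a mean log2 CPM of 6.80 in CTRL1 against 4.35 to 4.67, the cholesterol list 4.19 in PD3 against 3.73 to 3.77, and the immediate early list 3.65 in CTRL2 against 5.42 to 5.68. In oligodendrocytes HLA-C had 213 CPM in CTRL1 against 27.5 to 54.8, FAR2 54.9 CPM in CTRL1 against 18.6 to 23.6, and FOLH1 559 CPM in PD1 against 414 to 437. TRIM22 in astrocytes had 218 CPM in CTRL1 against 18.8 to 48.1. In microglia CCL2 had 1.03 CPM in AD2 against 0 in the others, from 1 UMI, and ALOX12-AS1 28.8 CPM in PD2 against 17.6 to 17.7. In OPC PRICKLE1 had 295.8 CPM in CTRL1 against 187 to 202, and BMPER 148 CPM in PD1 against 90.7 to 98.7. SNAP25-AS1 in MSN had 265 CPM in AD3 against 119 to 143.

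The donors were also split in every other way into the same group sizes. For microglia in AD against controls, 2 of 35 splits, the real one included, gave as many genes as the real 5, and the highest other split gave 19 genes (AD1, AD2, CTRL1 and CTRL3 on one side), so chance cannot be excluded. In the other 14 results the real count was 0, which 35 of 35 splits reach. The highest other splits for AD against controls gave 1 gene in oligodendrocytes, 0 in astrocytes, 0 in OPC and 1 in MSN. For PD against controls they gave 24 in oligodendrocytes, 3 in astrocytes, 1 in microglia, 109 in OPC and 1 in MSN. For AD against PD they gave 0 in oligodendrocytes, 2 in astrocytes, and 1 in microglia, OPC and MSN. The splits with 19, 24 (PD1, PD3, PD4 and CTRL2) and 109 genes (PD1, CTRL1, CTRL3 and CTRL4) point to a structure of the donors or libraries other than the diagnosis. For the lists, 33 were called in AD against controls, which 21 of 35 splits reach (highest other 43), 35 in PD against controls, which 18 reach (highest other 48), and 25 in AD against PD, which 22 reach (highest other 39), so chance cannot be excluded for any of these counts. The heat shock list was called in all 5 classes in 19 of 35 splits for PD against controls and in 19 of 35 for AD against PD. The interferon list was called in all 5 classes in 25 of 35 splits for AD against controls and in 24 of 35 for PD against controls, so chance cannot be excluded for either list.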

How the results depend on the processing

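The alternatives on linked libraries, on shared barcodes, on CTRL2 with PD4, on the macrophage-like part of the microglia and on unnamed nuclei were chosen after seeing the data. Among 7335 values of single genes and lists under other settings, 6970 kept direction and side of the threshold, 285 no longer passed, 56 newly passed and 24 changed sign, which for a list is the direction of its test. A gene that passed neither in the main fit nor under the other setting counts among the 6970, so that number says little of stability. Of the 93 list calls, 55 ended without at least 1 of the donors. Where no cause is given, the cause was not tested. The smallest sums per donor were those of microglia, with 120654 to 1074957 UMIs, and OPC, with 202541 to 722328.

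The count of 5 genes in microglia for AD minus CTRL was 27 by DESeq2, 242 with no filter beyond 1 count, 5 with RLE size factors, 0 with the stricter nuclei filter, 0 with the depth covariate, 0 with the library link as a term, 0 in the linked libraries alone, 2 without barcodes found in more than 1 library, 3 without CTRL2 and PD4, 0 without the macrophage-like part, and 0 to 21 without each donor in turn. Counts of 0 by edgeR became, by DESeq2, 7 in oligodendrocytes, 3 in astrocytes and 14 in MSN for AD minus CTRL, 3 in astrocytes, 4 in microglia, 9 in OPC and 14 in MSN for PD minus CTRL, and 6 in oligodendrocytes, 1 in astrocytes, 2 in microglia and 1 in MSN for AD minus PD. With no filter they became 2 in oligodendrocytes and 45 in OPC for AD minus CTRL, 1 in astrocytes, 108 in microglia and 56 in OPC for PD minus CTRL, and 3 in oligodendrocytes, 1 in astrocytes, 65 in microglia and 7 in OPC for AD minus PD. The depth covariate gave 1 in oligodendrocytes for AD minus PD, and the linked libraries alone 2 in MSN for AD minus CTRL. Without each donor in turn the count ranged from 0 to 1 in oligodendrocytes and 0 to 2 in MSN for AD minus CTRL, and from 0 to 2 in OPC and 0 to 2 in MSN for PD minus CTRL. With the donor number as a replicate block, microglia gave 0 genes for AD minus CTRL, the lists called were 34, 37 and 31 against 33, 35 and 25, and of 411 single values 402 kept direction and side and 9 no longer passed. Donors with the same number deviated together (r over 0.1) in 4 of 12 pairs in oligodendrocytes, 5 of 12 in astrocytes, 2 of 10 in microglia, 6 of 12 in OPC and 1 of 10 in MSN. These counts were not set beside those of differently numbered donors. Whether equal numbers mark a shared batch therefore stays open. Lists called with an estimated correlation were 0, 0 and 0 with all donors, and the only ones under another setting were the interferon list in OPC without CTRL1 for AD minus CTRL (adjusted p = 0.0248) and PD minus CTRL (0.0426). The exact p of the D1-type share was 0.118 with all donors and ranged from 0.0177 without CTRL3 to 0.389 without each donor in turn. With controls split between contrasts, r between the AD and PD fold changes averaged 0.000926 in oligodendrocytes, 0.0799 in astrocytes and 0.0514 in OPC.

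Signs changed as follows, in log2 fold change or list median. Without each donor in turn for AD minus CTRL, the interferon list in oligodendrocytes ranged from −1.96 to 0.36 and ISG15 from −5.45 to 0.30, and in MSN the interferon list ranged from −1.75 to 0.090 and AQP4 from −1.70 to 0.049, each highest without CTRL1. LUZP2 in oligodendrocytes ranged from −2.73 to 0.17 for PD minus CTRL, again highest without CTRL1. In astrocytes for AD minus CTRL, oxidative phosphorylation ranged from −0.13 to 0.79 and NDUFS6 from −0.077 to 1.52, lowest without AD2. The ribosomal list ranged from −0.20 without PD1 to 0.91 in astrocytes for PD minus CTRL, and from −0.90 to 0.090 without PD1 in microglia for AD minus PD. The unfolded protein response in microglia ranged from −0.96 to 0.40 without CTRL3 for AD minus CTRL. The activated list in microglia for AD minus CTRL was −0.11 without the macrophage-like part. In MSN for AD minus PD, GFAP ranged from −2.31 to 0.41 and AQP4 from −1.88 to 0.035, highest without PD4, and without CTRL2 and PD4 they were 0.41 and 0.035. In oligodendrocytes the linked libraries alone gave 0.14 for the interferon list and 0.20 for ISG15 in AD minus CTRL. In PD minus CTRL they gave −0.012 for the interferon list and 0.14 for HLA-E. They gave 0.14 for IER2 in astrocytes and 0.0080 for PSMB9 in microglia for PD minus CTRL, and in MSN 0.091 for the interferon list and 0.095 for MX1 for AD minus CTRL and 0.027 for GFAP for AD minus PD.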

Other observations

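The values in this part come from no planned comparison, and cluster sizes include predicted doublets unless said otherwise. Microglia split at the higher clustering resolution into 1337 and 590 nuclei, and the smaller part was led by F13A1, CD163, MSR1 and MRC1, genes known from macrophages, with 53.7% of its nuclei from CTRL1 and 10.2% predicted doublets. Among astrocytes, a cluster of 415 nuclei was led by CD44 and TNC, and a cluster of 1199 nuclei by metallothioneins, with 53.1% from AD2. A cluster of 2337 oligodendrocytes was led by the small chaperone gene CRYAB, with 46.2% from AD2. A cluster of 1153 oligodendrocytes was led by ISG15 and IFIT3, with 95.7% of its nuclei from CTRL1. Without predicted doublets, T cells numbered 80, led by THEMIS, SKAP1 and the cytotoxic genes GNLY and NKG7, and ependymal cells 149. The groups were compared within none of these clusters but the larger part of the microglia.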
